A study of Homo sapiens with 4 samples.

How the data were processed

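H3K27ac HiChIP, which captures pairs of DNA segments ligated in fixed nuclei and enriched for acetylated lysine 27 of histone H3, had been run on 4 untreated colorectal cancer cell lines (HCT116, LS513, SW480 and SW620), with 1 library per line. Per the labels, cells were fixed with 1% formaldehyde for 10 minutes, quenched in 0.125 M glycine for 5 minutes, cut with MboI, filled in with biotin, ligated, immunoprecipitated and made into libraries with Tn5 transposase. Per the submitters' processing notes, HiC-Pro was used and the genome build was hg19 (GRCh37), with no version of the tool recorded there. The loop caller, the peak caller and the source of the loop anchors are not given in the sources used here.

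The deposited values were whole-number counts of paired-end tags (PETs) for pairs of anchors, in 4 tables per library. The first deposited table held counts of pairs on 1 chromosome, pairs of an anchor with itself included. The second held the filtered pairs, whose anchor midpoints lay 5 kb to 2 Mb apart when checked. The third held counts of pairs on different chromosomes. The fourth deposited table, named for the mango model, repeated the filtered counts and added a number between 0 and 1 per loop, read here as the authors' p-value adjusted to an FDR because it fell as the PET count rose. Its column carries no header. Chromosomes 1 to 22 and X were used.

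No annotation of the hg19 build was used, and the gene table at hand follows GRCh38.p14, whose coordinates were not converted. No gene was therefore assigned to any anchor. The promoter counts, the 18 gene lists and the promoter-anchored share of loops planned before the data were examined were not run. The plan named 1 Mb windows as the measured unit in that case, and these are reported. A window's PETs were those of filtered loops with an anchor midpoint in it, each loop counted once, per 1000000 filtered PETs of the library (normalised PETs). Where an alternative kept only some loops, its rates were per 1000000 PETs of the loops it kept. At anchors overlapping in all 4 libraries, 3 PETs were thus 441 per 1000000 in SW480 and 121 in SW620. With all filtered loops they were 216 and 19.7. Ratios between these libraries at such anchors therefore differ from ratios per filtered PETs.

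With 1 library per line there was no significance test and no spread between replicates. A window was called higher where the exact conditional (Clopper-Pearson) 95% interval of its ratio to the highest of the other 3 libraries lay above 1, and lower where the interval of its ratio to the lowest of them lay below 1. The higher library needed at least 10 PETs. For SW620 against SW480 the ratio was that of the 2 libraries. Where the other libraries had equal rates, such as 0, the shallowest was taken. A count of 0 was set to a floor of 3 counts for a fold. Intervals and floors cover counting error only, since each line had 1 library. The intervals also treat PETs as independent, while PETs carry no molecular identifiers. The text names, for each line, the 5 windows with the highest lower bound and the 2 with the lowest upper bound, 8 windows each way for SW620 against SW480, and the 3 loops with most PETs per line. Calls expected from counting error were taken from 100 simulations with equal rates in all libraries.

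Loop sharing was measured after thinning each library to the filtered PETs of the shallowest, in 20 seeded draws, with both anchors overlapping by at least 1 bp. Beside it stands the share for random anchor pairs of the same chromosome and distance bin (12 bins). These were drawn from the loop anchors of the same library before thinning, and pairs that were real loops of that library were not removed. Anchor sharing used the same overlap. Interchromosomal counts were set against an expectation from the chromosome totals that leaves out pairs within a chromosome.

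The window calls, the sharing measure and the chromosome pair expectation were tested on simulated data first. With 200 of 2237 windows changed 4-fold in SW480, 57.7% of the raised windows were called higher and 24.3% of the lowered windows lower. With the same changes in LS513 these shares were 64.8% and 35.9%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Filtered PETs ranged from 13885 to 222113 per library, so that a count of 0 allowed up to 216 normalised PETs in SW480 and 13.5 in LS513. Alternatives fixed before the data were examined covered window size, a minimum of 2 PETs per loop, scaling by chromosome, overlap rules, thinning and FDR thresholds. The restriction to anchors overlapping in all 4 libraries, thinning of the window counts, leaving out SW480, every alternative for SW620 against SW480 and the comparison of HCT116 with LS513 at identical anchors were chosen after seeing the data.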

Results

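Chromatin loops at H3K27ac, a mark of active promoters and enhancers, were compared between 4 untreated colorectal cancer cell lines with 1 library each. SW480 and SW620 are textbook derivatives of the primary tumour and a lymph node metastasis of the same patient, while HCT116 and LS513 come from unrelated tumours. The filtered loop tables held 40696 loops with 81579 PETs in HCT116, 74401 loops with 222113 PETs in LS513, 7024 loops with 13885 PETs in SW480 and 62104 loops with 152421 PETs in SW620. SW480 was thus 16.0 times shallower than LS513. No replicate was given for any line, so no difference below has a replicate check.

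Most PETs joined an anchor with itself, from 78.7% in SW620 to 87.4% in HCT116. Loops with a single PET made up 66.5% of the filtered loops in HCT116, 57.0% in LS513, 64.3% in SW480 and 61.9% in SW620. The median loop span, weighted by PETs, was 66.8 kb in HCT116, 72.5 kb in LS513, 52.5 kb in SW480 and 67.7 kb in SW620. With each loop counted once it was 128, 187, 77.2 and 147 kb. With FDR under 0.01 and weighted by PETs it was 86.7, 70.8, 74.8 and 69.5 kb, where SW480 was not the shortest. The same loops counted once gave 170, 247, 120.5 and 187 kb, with SW480 the shortest. Interchromosomal PETs were 3.10% of all PETs in HCT116 (95% Clopper-Pearson interval 3.07 to 3.14), 3.90% in LS513 (3.87 to 3.93), 2.66% in SW480 (2.58 to 2.74) and 5.27% in SW620 (5.23 to 5.31). All PETs are those between a library's own anchors, which covered 65.6 Mb in SW480 and 160 Mb in SW620. Set against filtered loops instead, the order of the libraries changed, with HCT116 above LS513. At the authors' FDR under 0.01 the deposited tables held 5209 loops in HCT116, 13560 in LS513, 1020 in SW480 and 10661 in SW620, or 12.8%, 18.2%, 14.5% and 17.2% of the loops in each.

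The strongest loops differed between lines. In SW620 the loop with most PETs joined 50477903 to 50516519 with 50563592 to 50598111 on chromosome 16 (hg19). It held 210 PETs there, or 1378 normalised PETs (PETs per 1000000 filtered PETs of the library). Overlapping loops reached 2953 normalised PETs in SW480 (41 PETs), 90.0 in LS513 and 24.5 in HCT116, so this segment of chromosome 16 was high in both lines of the shared patient. SW620 also held 182 PETs between 1257783 to 1277238 and 1293154 to 1298590 on chromosome 16, with 0 overlapping loop PETs in the other 3 libraries. Between 50400413 to 50438124 and 50477903 to 50516519 it held 150 PETs (984 normalised), where SW480 had 19 (1368 normalised). In LS513 the leading loop, on chromosome 13 from 111153076 to 111185366, held 298 PETs, or 1342 normalised PETs, against 281.9 in HCT116. Its next loops lay on chromosome 3 from 195339764 to 195448674 (291 PETs, 31 in HCT116 and 0 in SW480 and SW620) and on chromosome 9 from 140078541 to 140138647 (230 PETs, 27 in HCT116, 25 in SW620 and 0 in SW480). In HCT116 the leading loop, on chromosome 18 from 3590146 to 3672527, held 90 PETs, and overlapping loops were present in all 4 libraries, at 1103 normalised PETs in HCT116, 522 in LS513, 3241 in SW480 and 538 in SW620. Its next loops, on chromosome 9 from 132306471 to 132377639 (87 PETs) and from 132218057 to 132348313 (80 PETs), had overlapping loops in LS513 and SW480 but 0 PETs in SW620. In SW480 the leading loop, on chromosome 7 from 73864149 to 73900363, held 60 PETs (4321 normalised). Overlapping loops held 24 PETs in HCT116 (294 normalised) and 124 in LS513 (558 normalised), while SW620 had 0. Whether a library had separate anchors at the places where it had 0 overlapping loop PETs was not checked. The next loops of SW480 were present in SW620 too, at fewer normalised PETs. On chromosome 17 from 63551487 to 63609729 SW480 held 42 PETs (3025 normalised) and SW620 141 (925 normalised). On chromosome 16 from 50477708 to 50590722 SW480 held 41 PETs (2953 normalised) and SW620 260 (1706 normalised).

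The share of loop PETs by chromosome set SW480 apart. Chromosome 19 held 2.41% of the filtered PETs in SW480, against 10.2% in HCT116, 9.53% in LS513 and 6.85% in SW620. Chromosome 16 held 2.08% in SW480 and 7.05% in SW620, and chromosome 22 held 1.09% and 2.99%. Chromosomes 2, 12 and 18 went the other way, with 9.21%, 9.25% and 2.67% of the PETs in SW480 and 5.26%, 6.44% and 0.794% in SW620. Chromosome 13 held 1.19% of the PETs in HCT116 and 2.60% in LS513.

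**Figure D1:**
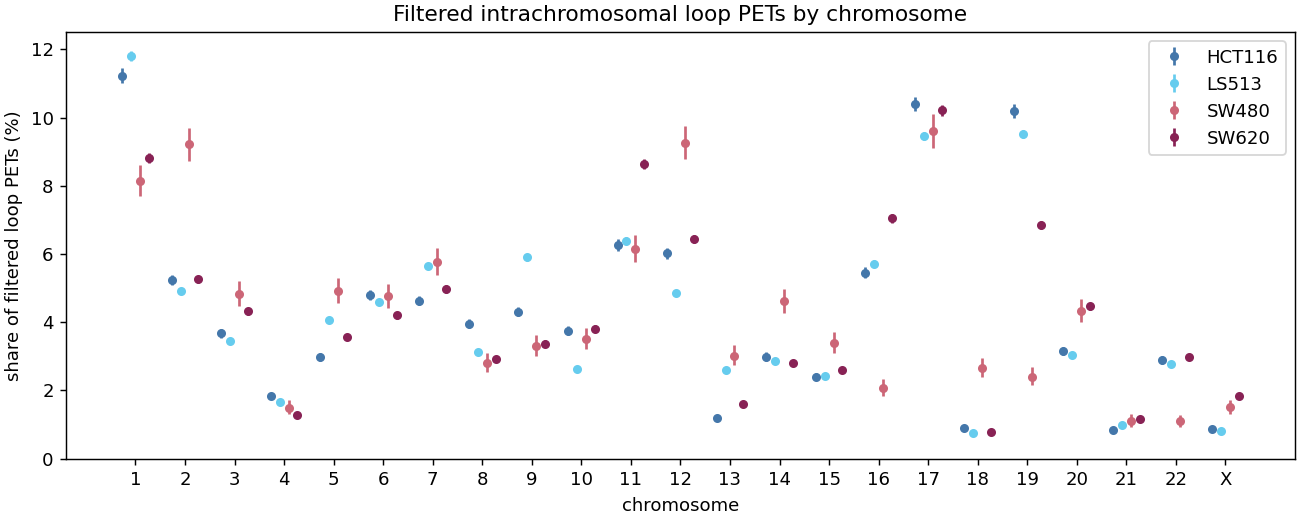
Share of filtered intrachromosomal loop PETs (percent, y axis) on each chromosome (x axis) in the 4 libraries; points are the shares and bars the 95% Clopper-Pearson intervals. SW480 lies lowest on chromosome 19 (2.41%) and highest on chromosome 18 (2.67%).

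Loops were shared between lines more often than random anchor pairs of the same chromosome and distance. The random pairs were drawn from a library's loop anchors before thinning. SW620 had 22207 such anchors and 11057 in the first thinned draw, while SW480 had 6116 in both. Ratios to random pairs therefore cannot be compared between libraries of different depth. Real loops of the library were also left among the random pairs, which can raise the random share and lower the ratio. With the filtered PETs of each library thinned to those of SW480, which left 10752 loops in HCT116, 10641 in LS513 and 10884 in SW620 in the first draw against 7024 in SW480, 23.7% ± 0.280 (technical SD over 20 thinning draws) of HCT116 loops were found in LS513, and 10.3% of random pairs. The reverse share was 23.9%, and 9.69% for random pairs. SW480 loops were found in SW620 at 18.8% ± 0.324 (random 12.8%), in HCT116 at 13.8% (random 9.02%) and in LS513 at 13.3% (random 8.75%). SW620 loops were found in SW480 at 10.9% (random 3.61%), in HCT116 at 17.6% (random 5.74%) and in LS513 at 17.3% (random 5.76%). HCT116 loops were found in SW620 at 18.4% and in SW480 at 8.61%, and LS513 loops at 18.3% and 8.37%. SW480 loops were thus found most often in SW620, but so were random pairs, and the ratio of the shares was 1.46 for SW620, 1.53 for HCT116 and 1.52 for LS513. With real loops left among the random pairs, these ratios do not decide whether SW480 shared more loops with SW620.

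**Figure D2:**
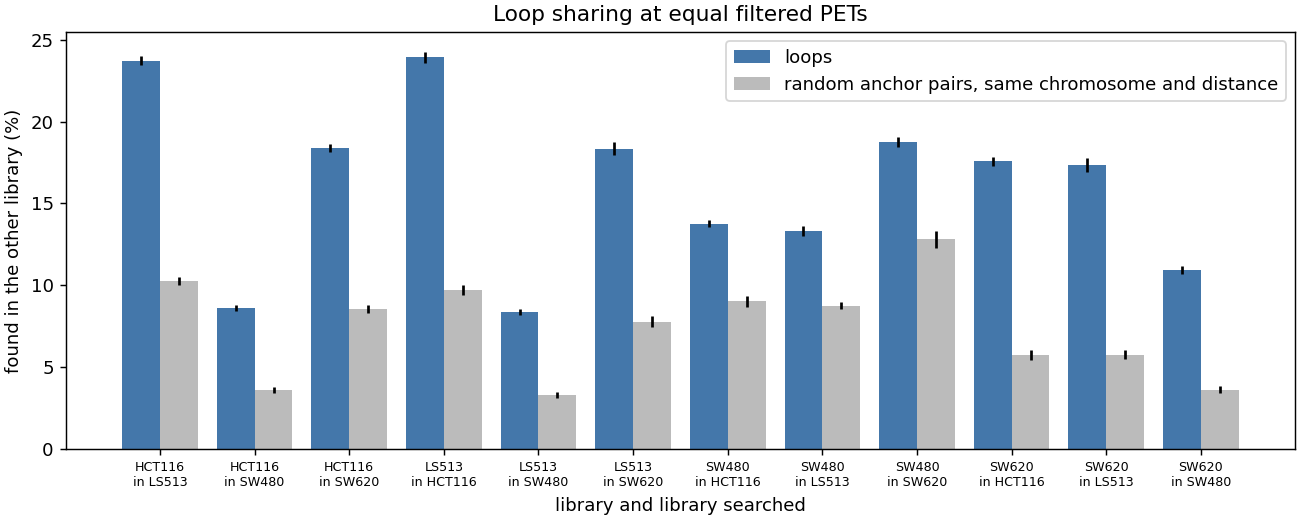
Percent of the loops of the first library found in the second (y axis) for the 12 ordered pairs of libraries (x axis) after thinning to equal filtered PETs, beside random anchor pairs of the same chromosome and distance; bars are means and whiskers technical SDs over 20 draws. HCT116 and LS513, which have nearly the same anchors, share most at 23.7% and 23.9%. Random pairs were drawn from anchors before thinning, with real loops not removed, so ratios to them are not ranked between libraries.

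Anchors differed in a way that bears on every comparison of regions. Of the anchors in all tables, 21821 were identical in HCT116 and LS513, which is 99.5% and 98.5% of their anchors. SW480 and SW620 had 527 identical anchors. SW480 had 9350 anchors covering 65.6 Mb, against 24556 covering 160 Mb in SW620. Among anchors of filtered loops, 75.9% of those of SW480 overlapped one of SW620, 59.2% one of LS513 and 56.8% one of HCT116. In the other direction, 20.4% of SW620 anchors overlapped one of SW480.

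HCT116 and LS513 could be compared at one anchor set, a comparison chosen after the anchors were seen. Of 2112 windows of 1 Mb, 244 were higher in HCT116 and 230 lower, against means of 27.4 and 29.5 in simulations with equal rates. HCT116 was higher at several places on chromosome 8, by 5.87-fold at 94 to 95 Mb (interval 4.16 to 8.39), 4.27-fold at 128 to 129 Mb (3.62 to 5.04) and 3.32-fold at 126 to 127 Mb (2.56 to 4.31). It was also 5.28-fold higher at 8 to 9 Mb of chromosome 1 (4.69 to 5.94) and 3.31-fold higher at 114 to 115 Mb of chromosome 10 (2.68 to 4.09). Scaling by the PETs of the chromosome gave 4.62, 3.36 and 2.61 for the windows of chromosome 8 in that order. It gave 5.54 on chromosome 1 and 2.32 on chromosome 10. LS513 was higher on chromosome 13, by 3.03-fold at 111 to 112 Mb (2.52 to 3.68), 3.22-fold at 113 to 114 Mb (2.51 to 4.17) and 2.75-fold at 28 to 29 Mb (2.12 to 3.61). Scaled by the PETs of the chromosome, these 3 folds fell to 1.39 (1.15 to 1.69), 1.48 (1.15 to 1.91) and 1.26 (0.972 to 1.65), the last no longer called, and chromosome 13 as a whole held 2.60% of the PETs in LS513 and 1.19% in HCT116. LS513 was also 2.96-fold higher at 1 to 2 Mb of chromosome 11 (2.37 to 3.73) and 2.75-fold higher at 1 to 2 Mb of chromosome 5 (2.04 to 3.77), and scaled in that way 2.89-fold and 2.03-fold.

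Against all other lines, HCT116 was higher in 84 windows and lower in 30. Its highest windows were 8 to 9 Mb of chromosome 1 (844 PETs, 5.28 times the next library, interval 4.70 to 5.94) and 128 to 129 Mb of chromosome 8 (375 PETs, 4.27 times, 3.62 to 5.05), followed by chromosome 2 at 132 and 227 Mb and chromosome 8 at 129 Mb. It was lowest at 80 to 81 Mb of chromosome 13 and 101 to 102 Mb of chromosome 14, with 5 PETs in each. The call on chromosome 13 was lost when scaled by chromosome, with SW480 (4 PETs) as the library compared, and that on chromosome 14 at overlapping anchors (3 PETs against 4 in SW480), where 8 to 9 Mb of chromosome 1 kept 4 PETs against 5 in SW480. LS513 was higher in 121 windows and lower in 42. It led at 113 to 114 Mb (622 PETs, 3.22 times HCT116, 2.51 to 4.17), 111 to 112 Mb (1031 PETs, 2.59 times SW620, 2.27 to 2.97) and 42 to 43 Mb of chromosome 13, at 146 to 147 Mb of chromosome 1 and at 1 to 2 Mb of chromosome 11. Scaled by chromosome, the windows at 113 and 111 Mb were at 1.47 and 1.38 times HCT116, then the highest other library in both, and the call at 42 Mb was lost. At anchors overlapping in all 4 libraries the window at 111 Mb turned to 0.258 times SW620, with 10 PETs against 29. LS513 was lower at 126 to 127 Mb of chromosome 8 (fold 3.32 below the next library) and at 129 to 130 Mb of chromosome 6 (2 PETs against 10 in HCT116), the latter not called with loops of at least 2 PETs. LS513 was higher in 22 of the 91 windows of chromosome 9 and 12 of the 62 of chromosome 13. In the windows higher in HCT116, the median anchor length was 84.7 kb in HCT116 and 84.0 kb in the library compared, and the median ratio was 1.68 for PETs and 1.65 for PETs per kb of anchor. In LS513 these ratios were 1.65 and 1.60. At anchors overlapping in all 4 libraries, where 868 windows had PETs, 23 were higher in HCT116 and 34 in LS513. Without SW480 the counts were 136 higher and 73 lower in HCT116, and 160 and 98 in LS513. With PETs thinned to the shallowest library in a single draw they were 14 and 6 in HCT116 and 23 and 7 in LS513, and the named windows on chromosome 2, at 80 and 42 Mb of chromosome 13 and at 146 Mb of chromosome 1 were not called.

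SW620 was higher than all other lines in 192 windows and lower in 67. It led at 92 to 93 Mb of chromosome 5, with 118 PETs against 4 in LS513, 1 in HCT116 and 0 in SW480 (43.0 times LS513, interval 16.4 to 160). The next windows were 86 to 87 Mb of chromosome 15 (15.7 times LS513, 6.34 to 50.4), 53 to 54 Mb of chromosome 8 (11.3 times LS513, 5.64 to 25.8), 70 to 71 Mb of chromosome 11 (8.32 times HCT116, 5.50 to 13.2) and 1 to 2 Mb of chromosome 20 (7.25 times LS513, 5.04 to 10.7). SW480 held 0 PETs in the first 3 of these windows, which allowed up to 216 normalised PETs there, so SW480 bounds these differences less tightly than LS513. With loops of at least 2 PETs the window of chromosome 15 was not called, since SW480 with 0 PETs became the library compared. SW620 was lowest at 115 to 116 Mb of chromosome 12, with 3 PETs against 29 in HCT116 and 158 in LS513 (not called when scaled by chromosome, against 5 PETs in SW480), and at 61 to 62 Mb of chromosome 1, with 0 PETs, at least 7.09-fold lower than LS513. Chromosomes X and 11 each held 20 of the windows higher in SW620, out of 97 and 102 windows. The part was larger on chromosomes 20 (14 of 56), 22 (8 of 35) and 16 (14 of 66). In the windows higher in SW620 the median anchor length was 121 kb in SW620 and 50.0 kb in the library compared. The median ratio was 1.99 for PETs and, in the 189 windows with anchors in both, 0.937 per kb of anchor. A ratio of 1 per kb is not neutral, since rates are per library and SW620 had the longest total anchor length. At anchors overlapping in all 4 libraries 37 windows were higher and 19 lower, and without SW480 the counts were 427 and 305. Thinned to the shallowest library in a single draw they were 35 and 9, and the windows of chromosomes 15 and 8 named above, with 8 and 9 PETs left, and that of chromosome 12 were not called.

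SW480 was higher in 193 windows and lower in 245. The lower windows took the largest part of chromosomes 19 (35 of 56 windows), 22 (14 of 35), 16 (22 of 66) and 17 (21 of 75). At 2 to 3 Mb of chromosome 19 SW480 held 3 PETs against 771 in SW620, 623 in HCT116 and 1206 in LS513, a ratio of 0.0427 to SW620 (interval 0.00879 to 0.125). Scaled by chromosome the lowest other library was LS513, with a ratio of 0.158, and at overlapping anchors the ratio to SW620 was 0.332 and not called. At 75 to 76 Mb of chromosome 7 it held 0 PETs and was at least 9.41-fold lower than SW620. SW480 held 0 PETs in 81 of the 245 windows. Only anchors of filtered loops were counted, so these windows had no anchor by definition. Anchor length was thus not independent of the PETs. In the lower windows the median anchor length was 14.2 kb in SW480 and 127 kb in the library compared, and in the 164 windows with anchors in both the median ratio per kb of anchor was 1.16. In the windows higher in SW480 the median anchor length was 74.1 kb in SW480 and 79.7 kb in the library compared. The median ratio was 3.37 for PETs and, in the 191 windows with anchors in both, 3.95 per kb of anchor. A ratio of 1 per kb is not neutral here. Rates are per library, and all anchors covered 65.6 Mb in SW480 against 160 Mb in SW620. The less covered library thus has the higher rate per kb across the genome. SW480 was higher at 40 to 41 Mb of chromosome 7, with 34 PETs against 2 in SW620 (187 times, interval 47.8 to 1603). Thinned to the shallowest library this was 34 times, with 34 PETs against 1. Further windows were 219 to 220 Mb of chromosome 1, 3 to 4 Mb of chromosome 7 (16 PETs and 0 elsewhere) and 37 to 38 Mb of chromosome 18. The window at 196 to 197 Mb of chromosome 2 was not called with loops of at least 2 PETs, with 6 PETs left. Of the 180 windows of chromosome 2, 28 were higher in SW480, a part like that of chromosomes 12 (18 of 116), 14 (11 of 69) and 20 (9 of 56). At anchors overlapping in all 4 libraries, 25 windows were higher in SW480 and 17 lower, and with PETs thinned to the shallowest library 145 and 141.

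SW620 against SW480 set the metastasis line beside the primary line of the same patient. SW620 was higher in 382 windows and lower in 234, against means of 14.8 and 16.0 with equal rates. The largest rises were at 67 to 68 Mb of chromosome 16 (1121 PETs against 1, ratio 102, interval 18.3 to 4037), 62 to 63 Mb (780 against 3) and 0 to 1 Mb (626 against 2) of chromosome 11, and 1 to 3 Mb of chromosome 19 (798 against 4 and 771 against 3). SW480 held 0 PETs at 75 to 76 Mb of chromosome 16, 75 to 76 Mb of chromosome 7 and 42 to 43 Mb of chromosome 22, where SW620 was at least 9.87-fold, 9.41-fold and 9.38-fold higher. HCT116 and LS513 held at least 102 PETs in each of these windows. Scaled by chromosome, the folds with the floor were 2.91, 10.9 and 3.43. The ratio fell to 30.2 at 67 to 68 Mb of chromosome 16, 8.23 at 2 to 3 Mb of chromosome 19 and 6.39 at 1 to 2 Mb of chromosome 19. At overlapping anchors the calls at 0 to 1 Mb of chromosome 11 (1.23, 9 PETs against 2), 2 to 3 Mb of chromosome 19 (3.01, 33 against 3) and 1 to 2 Mb of chromosome 19 (0.958, 7 against 2) ended. Ratios at these anchors were scaled to each library's PETs at such anchors, not to its filtered PETs. The windows lower in SW620 were led by chromosome 2 at 12 and 196 Mb, chromosome 7 at 40 and 3 Mb, chromosome 1 at 219 Mb, chromosome 18 at 37 Mb, chromosome 14 at 25 Mb and chromosome 3 at 111 Mb. With loops of at least 2 PETs, 196 Mb of chromosome 2 and 25 Mb of chromosome 14 were not called, with 6 and 5 PETs left in SW480. At 111 to 112 Mb of chromosome 3 there were 6 PETs in SW620 and 25 in SW480. In windows higher in SW620 the median anchor length was 146 kb in SW620 and 14.2 kb in SW480. SW480 held 0 PETs, and so had no loop anchor by definition, in 122 of them. In the 260 with anchors in both, the median ratio per kb of anchor was 0.732. In the 230 such windows lower in SW620 it was 0.223. All anchors covered 65.6 Mb in SW480 and 160 Mb in SW620, so a ratio of 1 per kb is not neutral. With loops at anchors overlapping in all 4 libraries, 71 windows were higher and 57 lower, and with PETs thinned to the shallowest library 250 and 195. Of the 234 windows lower in SW620 with all loops, 152 had at least 10 PETs in a library at these anchors, 46 were again lower and 10 higher; of the 382 higher windows these counts were 157, 41 again higher and 2 lower.

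**Figure D3:**
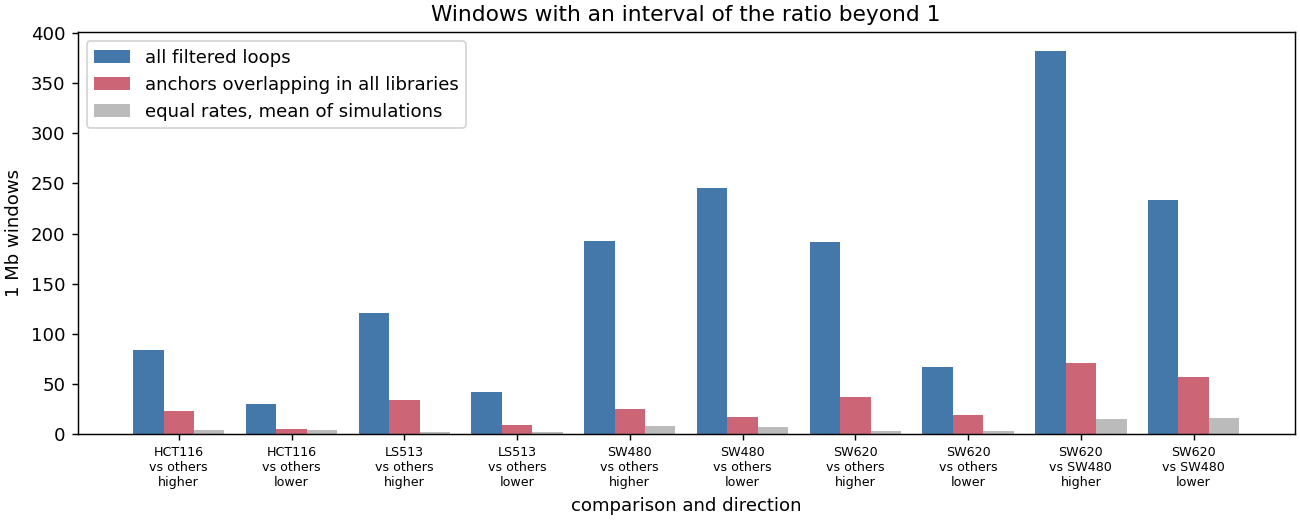
Number of 1 Mb windows (y axis) called higher or lower in each comparison (x axis) with all filtered loops, with loops at anchors overlapping in all 4 libraries, and as the mean of 100 simulations with equal rates. Of the 245 windows lower in SW480, 114 had at least 10 PETs in a library at overlapping anchors, and 7 were called lower and 2 higher there. Rates at overlapping anchors were scaled to each library's PETs at such anchors.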

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

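All tests in this part were chosen after the patterns were seen. In the interchromosomal counts, which the window comparisons do not use, chromosomes 5 and 20 were picked from all 253 chromosome pairs after these were seen. By the lower bound of the observed to expected ratio, not by the ratio itself, they ranked 1 in SW480 and 4 in SW620. Chromosomes 10 and 16 ranked 2 in SW480 (17 PETs, 2.03, 1.18 to 3.25) and 8 in SW620 (1.25, 1.14 to 1.38), with HCT116 at 1.09 and LS513 at 0.836. They were not examined further. Between chromosomes 5 and 20 SW480 held 48 PETs and SW620 327, at 2.02 (95% Poisson interval 1.49 to 2.67) and 1.35 (1.20 to 1.5) times the expectation from chromosome totals, while HCT116 was at 0.988 and LS513 at 0.938. A few anchor pairs with many PETs did not account for it, since with each pair counted once the lower of the SW480 and SW620 ratios was still 1.36. A joined segment of both chromosomes in both lines stays open. The pair of 20 Mb blocks with the highest lower bound in SW620 had 1 PET in SW480, a ratio of 2.80 (interval 0.071 to 15.6). The block pair with the highest lower bound in SW480 was 80 to 100 Mb of chromosome 5 with 40 to 60 Mb of chromosome 20 (7 PETs, 8.43, 3.39 to 17.4). It was at 1.61 in SW620 (0.737 to 3.06). Another block pair, 140000001 to 160000000 of chromosome 5 with 20000001 to 40000000 of chromosome 20, had intervals above 1 in both lines. It was at 4.73 in SW480 (5 PETs, 1.535 to 11.03) and 2.34 in SW620 (21 PETs, 1.449 to 3.578). HCT116 was at 1.172 and LS513 at 0.5327 there. This block pair was picked from all block pairs after these were seen, so it does not decide the question.

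One interchromosomal anchor pair, 16969123 to 16972781 on chromosome 1 with 49726009 to 49728817 on chromosome 3, held 166 PETs in HCT116 and 206 in LS513 and 0 in the other libraries. On chromosome 17, a pair 43660113 to 43664159 with 62914929 to 62917132 held 47 PETs in HCT116, 168 in LS513, 84 in SW480 and 170 in SW620, beyond the 2 Mb limit of the filtered loops. No explanation was tested for either pair.

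SW480 held 55.4% of its window PETs in the 447 of 2237 windows with most HCT116 anchors, against 65.2% in SW620, 72.6% in HCT116 and 72.9% in LS513. These windows were ranked by an anchor set that only HCT116 and LS513 share, which favours both. Loss of whole chromosomes alone would not lower the share of SW480 within chromosomes. With windows ranked by HCT116 anchors within each chromosome, SW480 had the lowest share on 18 of 23. This only just met the bound for excluding that loss alone, a bound written after the pattern was seen. A part played by whole chromosomes was not excluded, and loss of arms was not tested. Fewer anchors placed in SW480 could not be decided: at anchors overlapping in all 4 libraries its share against the lowest other was -0.0724 on the log2 scale, and -0.234 with all loops, but the bound set to exclude this (-0.5) lay beyond the pattern itself. Fewer loops without fewer reads stayed open for the same reason, at -0.120 for same-anchor PETs.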

How the results depend on the processing

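The promoter and gene list alternatives were not run, because no hg19 annotation was used. No paired analysis was possible because each line had 1 library. The causes of the moves below were not tested, except that thinning and stricter filters leave fewer PETs. Window counts are given as higher, then lower. Chosen after seeing the data, loops at anchors overlapping in all 4 libraries, scaled to their own PETs, gave 23 and 5 windows in HCT116, 34 and 9 in LS513, 25 and 17 in SW480, 37 and 19 in SW620, and 71 and 57 for SW620 against SW480. Thinning to the shallowest library in a single draw, also chosen then, gave 14 and 6 in HCT116, 23 and 7 in LS513, 35 and 9 in SW620, 141 lower in SW480 and 250 higher in SW620 than in SW480. Without SW480, likewise, HCT116 had 136 and 73, LS513 98 lower, and SW620 427 and 305. With 500 kb windows 128 were higher in HCT116, and with loops of at least 2 PETs 47 were lower there. At overlapping anchors the ratio for 111 to 112 Mb of chromosome 13 in LS513 turned to 0.258 (10 PETs against 29 in SW620). It also lay below 1 for 8 to 9 Mb of chromosome 1 in HCT116 (0.440, 4 PETs against 5 in SW480) and 1 to 2 Mb of chromosome 19 in SW620 against SW480 (0.958, 7 PETs against 2), too few PETs for a direction. Of the other named windows, 2 were still called and 4 were not: 101 to 102 Mb of chromosome 14 in HCT116, 2 to 3 Mb of chromosome 19 in SW480 and in SW620 against SW480, and 0 to 1 Mb of chromosome 11 in SW620 against SW480. The rest had too few PETs there. Scaling by chromosome kept 41 of the 44 named windows called and lost 80 to 81 Mb and 42 to 43 Mb of chromosome 13 and 115 to 116 Mb of chromosome 12. It kept 14 windows named for HCT116 against LS513 at identical anchors and lost 2, at 28 and 114 Mb of chromosome 13. Thinning kept 33 named windows and lost 8: chromosome 2 at 132 and 227 Mb, chromosome 13 at 80 and 42 Mb, chromosome 1 at 146 Mb, chromosome 15 at 86 Mb, chromosome 8 at 53 Mb and chromosome 12 at 115 Mb. Loops with at least 2 PETs kept 34 and lost 5: chromosome 6 at 129 Mb, chromosome 15 at 86 Mb, chromosome 14 at 25 Mb, and chromosome 2 at 196 Mb in both comparisons that name it. The remaining named windows had too few PETs for a ratio.

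The median loop share over the 12 ordered pairs was 17.4% and became 27.6% with FDR under 0.01 unthinned, 18.5% with at least 2 PETs, 33.3% unthinned, 8.07% with a reciprocal overlap of 50% and 22.2% within 5 kb. In the same order, SW480 loops were found in SW620 at 48.1%, 14.5%, 46.9%, 7.45% and 25.0%, and SW620 loops in SW480 at 4.93%, 18.6%, 5.51%, 4.80% and 13.8%. HCT116 loops in LS513 were at 53.6%, 26.6%, 62.1% and, within 5 kb, 31.4%; LS513 loops in HCT116 at 20.6%, 26.5%, 34.0% and 31.5%. The median anchor share, 59.9%, became 62.0% with at least 2 PETs, 43.9% with reciprocal overlap and 49.8% thinned. SW620 anchors in SW480 were at 14.5%, 13.4% and 27.6%, SW480 anchors in SW620 at 48.6% with reciprocal overlap and 53.8% thinned, HCT116 anchors in LS513 at 92.6% with at least 2 PETs and 65.2% thinned, and LS513 anchors in HCT116 at 65.2% and 67.3%.

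Counting each loop once raised the median span to 128 kb in HCT116, 187 kb in LS513, 77.2 kb in SW480 and 147 kb in SW620. Weighted by PETs, it was 86.7, 70.8, 74.8 and 69.5 kb with FDR under 0.01, and 85.8, 94.5, 62.4 and 83.6 kb with all pairs of different anchors. The interchromosomal share was 0.0821%, 0.0878%, 0.0359% and 0.0938% for pairs with at least 2 PETs, and 27.3%, 23.1%, 22.3% and 27.1% against filtered loops. In the same order, 22336, 38190, 3170 and 34773 loops passed an FDR under 0.05, and 1971, 6217, 405 and 4573 passed 0.01 with at least 4 PETs. SW480 had 644 loops under 0.001. Results of SW480 from filtered loops rest on 13885 filtered PETs, the depth that limits every comparison of such loops with it. Its interchromosomal share of all PETs rests on 149829 PETs.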
